A study of Homo sapiens with 16 samples.

How the data were processed

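RNA was counted in 16 libraries of HEK293 cells in 8 groups of 2, made from 2 receptor genotypes (wild-type and optimized) and 4 treatments (untreated, IFNw, H11 and IFNL3). Per the labels' protocols, cells received 100 nM of a ligand for 15 min, total RNA was purified with a column kit, and libraries were made with an Ion Torrent 540 or 550 kit; which library used which is not given in the sources used here. The labels also give a time of 24 hr. Each deposited file holds whole-number read counts per target for one library, with no normalization, per the file headers and the values. The genome build was hg19, per the submitters' processing notes, and the aligner and counter are not given in the sources used here. Because the files pair each target with a gene symbol and an Entrez identifier, genes were used by symbol and no coordinates are given. The targets appear to be amplicons, whose positions and lengths are not given in the sources used here. Levels of different genes may therefore not compare, and the transcript lengths used below need not be the lengths counted. Whether counting used strand or split reads between near-identical genes is not given in the sources used here, so levels of histone, ribosomal protein, MHC class I and HSPA1A genes are uncertain in that respect.

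Of 20812 targets per file, 10 were spike-in controls with at most 1 read in any library and were left out, which left 20802. Spreadsheet software had turned 28 gene symbols into dates, and 27 were renamed from their Entrez identifier. Library totals lay between 5331203 and 9822088 reads. A count of 0 over a group was given an upper limit of 3 reads, and ratios on 1 to 3 reads have exact 95% intervals. Reads were not collapsed by molecule, so intervals and limits cover counting error only. Replicates of a group differed by more than sampling noise in all 8 groups (chi-square per degree of freedom 6.31 to 24.6), so none was treated as the same library deposited again. The least alike pair was untreated optimized cells (Pearson's r of log CPM 0.965 across genes, against 0.983 to 0.986 in the other groups).

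Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr on the 8 groups, TMM factors, quasi-likelihood fit and test). All 16 libraries entered one fit with a coefficient per group, so that groups of 2 shared an estimate of the spread (common dispersion 0.0176, a biological coefficient of variation of 13.3%). The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the 12704 genes tested. The 18 comparisons were each ligand against untreated cells within a genotype, optimized against wild-type cells within each treatment, the differences between the genotypes' responses to each ligand, H11 and IFNw against IFNL3 within a genotype, and optimized against wild-type cells averaged over treatments. These comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. H11 against IFNw in each genotype, the transcript length offset, the fit without the wild-type libraries with H11 and IFNL3 and a list of amino-acid response genes were added after the data were seen.

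The 26 gene lists were antiviral effectors, interferon signalling and feedback, RNA and DNA sensors, ISG15 conjugation, MHC class I antigen presentation, chemokines and IRF1-dependent genes, cell death and growth arrest, immediate early genes, NF-kappaB targets, interferon receptors and Janus kinases, interferon genes, unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol synthesis, mitosis, DNA replication, histones, ribosomal proteins, the respiratory chain, p53 targets, TGF-beta and WNT targets, and markers of blood cells, fibroblasts, hepatocytes with keratin-rich epithelium, and neurons. Of 581 list memberships, 577 matched a target by current or older symbol. Lists with 3 or more tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation was the alternative.

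For each comparison the rule for named genes took up to 10 genes in each direction with the largest fold changes among called genes whose libraries did not overlap between the groups (without that condition for the response differences and the average) and whose mean was 5 CPM or more in a compared group. It also took up to 5 called members of each list, the receptors and kinases by level, and a panel including MX1, IFIT1, IFI6, OAS1, ISG15, USP18, IRF9, CXCL10 and SOCS1 by level. The text names genes from these, and some that the rule took are not reported here.

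Alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no low-count filter, replicate number as a block, a fit of the compared groups alone, and each library left out in turn, where a lone library is assumed to vary like the other groups. The length offset removed from each library a natural spline (5 degrees of freedom) on log transcript length. It was fitted to log CPM minus each gene's mean over the libraries, on genes over a mean log2 CPM of 3 outside the interferon lists. Transcript lengths came from the GENCODE annotation of another build than the files use and were known for 12131 of the tested genes (95.5%). The tests were run on simulated counts with 200 changed genes before use. The changed genes were drawn from those at 5 CPM or more in untreated wild-type cells, so the shares below hold for such genes. For IFNw against untreated wild-type cells, 19.4% of 1.5-fold, 75.8% of 2-fold and 98.8% of 4-fold changes were recovered and 5.56% of calls were false. For optimized against wild-type cells with IFNw the shares were 18.8%, 72.2% and 99.7% with 5.79% false, and for the average over treatments 90.1%, 99.4% and 100% with 4.46% false.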

Results

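Gene expression was counted in 16 libraries of HEK293 cells, a human embryonic kidney line kept in Free-style medium. The cells carried either wild-type receptors or receptors that the labels call optimized, in a series about how the geometry between receptor-bound Janus kinases affects the response to type I and type III interferons. Cells of each genotype were left untreated or received 100 nM of IFNw (interferon omega, type I), IFNL3 (interferon lambda 3, type III) or H11, a variant of IFNL3 labelled as high-affinity. The labels give an exposure of 15 min and a time of 24 hr without saying how they relate. No mock-treated group is among the libraries used here, so any difference from untreated cells, and any gene count given for a ligand, may include a difference in handling. Each of the 8 groups had 2 libraries, called biological replicates in the labels with no word on separate cultures. The p-values of single genes therefore measure the spread between these libraries. Camera's p-values set the genes of a list against all other genes and are not a measure of that spread alone. Their size depends on the preset correlation between genes, and most are given for that setting only. Total counts ran from 5331203 reads in replicate 2 of untreated optimized cells to 9822088 reads in replicate 2 of optimized cells with IFNw, and 14033 to 15250 genes had a read. Of 20802 gene targets, 12704 were tested. Fold changes are log2 values ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and levels are CPM (normalised read counts scaled to library size, mean ± SD, n = 2).

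The receptor subunits and kinases were measured in all groups. IFNAR1 and IFNAR2, the type I receptor chains, lay between 11.6 and 19.2 CPM and between 27.9 and 36.9 CPM as group means. IFNLR1 (listed as IL28RA), the chain specific to type III interferons, lay between 1.93 and 3.25 CPM on 30 to 57 reads per group. IL10RB, its partner chain, was at 10.8 ± 1.60 CPM in wild-type cells with H11 and 11.5 ± 0.16 CPM with IFNL3, and between 19.8 and 24.0 CPM in the other groups. These levels are without the length offset, and those wild-type libraries had a length trend of their own, given below. Among the kinases, JAK1 lay between 7.16 and 7.38 CPM with IFNw in both genotypes and with H11 in optimized cells. In the other groups it lay between 13.6 and 15.6 CPM. TYK2 lay between 26.6 and 47.9 CPM and JAK2 between 2.45 and 5.73 CPM. The gamma interferon receptor chains lay between 23.7 and 47.4 CPM for IFNGR1 and between 42.3 and 72.0 CPM for IFNGR2, and EPOR, the erythropoietin receptor, between 3.09 and 7.14 CPM. The list of receptors and kinases, with 9 tested members that did not include IFNLR1, was not called in any comparison, its smallest adjusted p being 0.348 by camera. Single members were called in some comparisons, as JAK1 was with IFNw against untreated wild-type cells (-1.08 ± 0.28).

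The panel of interferon-stimulated genes was low in untreated cells and split by ligand and genotype after treatment. ISG15, a ubiquitin-like modifier, was at 18.1 ± 1.60 CPM in untreated wild-type cells and 15.2 ± 3.22 CPM in untreated optimized cells. It reached 7781 ± 106 CPM with IFNw, 586 ± 58.8 CPM with H11 and 558 ± 52.4 CPM with IFNL3 in wild-type cells, against 7518 ± 357, 7143 ± 542 and 4372 ± 4.09 CPM in optimized cells. IFI6, an antiviral mitochondrial and endoplasmic reticulum protein, followed the same order, with 7946, 694 and 659 CPM in wild-type cells and 8126, 8020 and 5214 CPM in optimized cells. IFIT1, which binds viral RNA, was at 2015, 680 and 723 CPM against 2088, 2117 and 1069 CPM. USP18, which removes ISG15 and dampens receptor signalling, was at 149, 94.9 and 93.7 CPM against 158, 153 and 143 CPM. MX1, a classical antiviral GTPase, stayed between 0.42 and 1.30 CPM on 7 to 28 reads per group. How well the MX1 target counts its transcripts was not tested, so these reads do not show that MX1 was not induced. The chemokine CXCL10 had 0 reads in both untreated groups, which allows up to 0.156 CPM in wild-type and 0.193 CPM in optimized cells. It had at most 2.67 CPM with a ligand. SOCS1 is not analysed here.

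**Figure D1:**
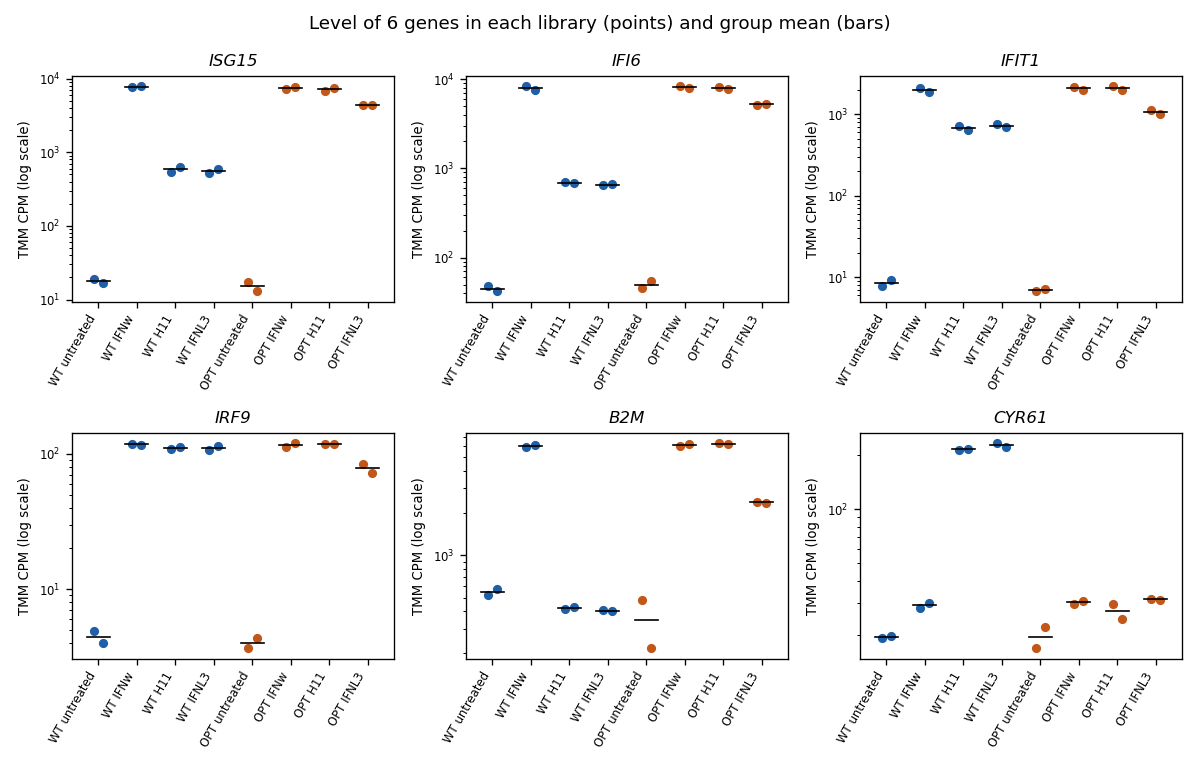
Normalised read counts (CPM, log axis) of ISG15, IFI6, IFIT1, IRF9, B2M and CYR61 in the 8 groups, with wild-type cells in blue and optimized cells in orange, a point per library and a bar at each group mean. ISG15 stood at 586 and 558 CPM in wild-type cells with H11 and IFNL3 and at 7143 and 4372 CPM in optimized cells, while IRF9 lay between 78.1 and 118 CPM in all 6 treated groups.

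IFNw raised antiviral genes by large factors in wild-type cells. IFI27, a small interferon-induced membrane protein, rose from 0.267 ± 0.236 CPM, on 5 reads, to 3731 ± 663 CPM (log2 13.73 ± 0.30). OAS1, a sensor of double-stranded RNA that starts RNA decay, rose by 10.55 ± 0.31 on the log2 scale from 5 reads, and ISG15 rose 430-fold (8.75 ± 0.18). IFI44 was at least 1976-fold higher and IFIT3, a partner of IFIT1, at least 503-fold higher, both from 0 reads in the untreated group. A transcript length offset lowered IFI27 to 13.08 and ISG15 to 8.09. IFI27 was at 15.003 and 13.02 without replicate 1 or 2 of untreated wild-type cells, and OAS1, whose untreated reads all lay in replicate 2, at 9.64 without replicate 1. RSAD2, the antiviral enzyme viperin, was 608-fold higher with a counting interval of 168 to 5028. Of 56 tested antiviral effectors 53 rose and 0 fell, also 53 adjusted over the list alone, with a median of 3.80, or 3.62 with genes of 0 to 3 baseline reads at their bound (camera, adjusted p = 4.2e-176).

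Signalling, sensing and antigen presentation genes rose with IFNw as well. IRF9, a DNA-binding factor of the interferon response, rose 26.4-fold (4.72 ± 0.16), USP18 7.41-fold (2.89 ± 0.15) and IRF7, which drives interferon genes, by 4.88 ± 0.24. In the list of signalling and feedback genes 10 of 16 rose and 2 fell (10 and 4 adjusted over the list alone, camera adjusted p = 5.0e-13). The RNA sensors IFIH1 (MDA5) and DDX58 (RIG-I) rose by 5.85 ± 0.30 (6.66 without replicate 1 of untreated wild-type cells) and 3.71 ± 0.16. Of 7 sensors 5 rose and 1 fell (also 5 and 1 adjusted over the list alone, camera adjusted p = 4.9e-12). All 6 tested genes of ISG15 conjugation rose (also 6 adjusted over the list alone), including its activating enzyme UBA7 (4.85 ± 0.36) and its ligase HERC5 (2.44 ± 0.16). Its camera adjusted p was 7.1e-41. MHC class I presentation rose in 16 of 19 genes (also 16 adjusted over the list alone, median 2.16, camera adjusted p = 8.0e-33). The immunoproteasome subunits PSMB9 and PSMB8 were at 4.75 ± 0.19 (4.11 with a length offset) and 3.10 ± 0.13 and the class I light chain B2M at 3.46 ± 0.23. Of 9 chemokines and IRF1-dependent genes 6 rose and 0 fell (8 adjusted over the list alone, camera adjusted p = 0.0016, and adjusted p = 0.021 with an estimated correlation), among them the death ligand TNFSF10 at 3.34 ± 0.45 (2.75 without replicate 2 of cells with IFNw).

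Genes outside the interferon pathway also changed with IFNw in wild-type cells. Cholesterol synthesis rose in 14 of 21 genes (17 up and 1 down adjusted over the list alone, median 0.83, camera adjusted p = 6.7e-07). The isoprenoid isomerase IDI1 was at 1.94 ± 0.11 and the sterol oxidase MSMO1 at 1.05 ± 0.12. Heat shock genes rose in 9 of 18 (10 adjusted over the list alone, median 0.31, camera adjusted p = 4.2e-05), and respiratory chain subunits in 22 of 40 with 1 fall (24 and 1 adjusted over the list alone, median 0.75, or 0.30 with a length offset, camera adjusted p = 4.9e-08). The unfolded protein response list went both ways, with 7 members up and 9 down of 24 (7 and 10 adjusted over the list alone, median -0.23, camera adjusted p = 0.0069), and was no longer called without the low-count filter (median -0.22). Its median was -0.15 with a length offset. Those that fell included CHAC1, which degrades glutathione, SESN2, a stress-induced regulator of growth signalling, ASNS, asparagine synthetase, and DDIT4, an inhibitor of growth signalling, at -4.10 ± 0.21, -2.05 ± 0.14, -1.92 ± 0.14 and -1.86 ± 0.18. SDF2L1, part of an endoplasmic reticulum chaperone complex, was at 1.54 ± 0.21, or 0.94 with a length offset. INHBE, an inhibin beta chain, was 71.8-fold lower (counting interval 24.3 to 350), and SLC7A11, the cystine transporter, and STC2, a secreted glycoprotein, were at -2.46 ± 0.22 and -2.40 ± 0.16. Ribosomal protein genes rose in 24 of 52 and fell in 3 (26 and 3 adjusted over the list alone, median 0.50, camera adjusted p = 5.2e-05), but the median turned to -0.09 with a transcript length offset. A library's length trend is Spearman's rho, across genes, between transcript length and log CPM minus the gene's mean over all 16 libraries. Relative to that mean, levels in the IFNw libraries fell with transcript length (rho -0.42 and -0.43), against 0.14 and 0.16 in the untreated wild-type libraries. Genes are not independent replicates.

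In total, 2109 genes rose and 1879 fell with IFNw in wild-type cells, 3988 of the 12704 tested, and 1200 of the calls exceeded 2-fold. All genes named for this comparison passed at an adjusted p of 0.0075 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 2630 without replicate 2 of wild-type cells with IFNw, where JAK1 (-1.08 ± 0.28 with both) was no longer called at -0.99.

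H11 and IFNL3 raised signalling and antiviral genes in wild-type cells. IRF9 rose 24.8-fold (4.63 ± 0.16) with H11 and 24.7-fold (4.63 ± 0.16) with IFNL3. ISG15 rose 32.4-fold (5.02 ± 0.16) and 30.9-fold (4.95 ± 0.15), and OAS1 by 7.96 ± 0.33 and 8.09 ± 0.32 (7.05 and 7.18 without replicate 1 of untreated wild-type cells). IFIT3 was at least 441-fold higher with either ligand, and CMPK2, a mitochondrial nucleotide kinase induced by interferon, was 486-fold higher with H11 (counting interval 134 to 4019). Of the 56 antiviral effectors 49 rose and 0 fell with each ligand (50 and 51 adjusted over the list alone), with medians of 3.20 and 3.11, or 2.85 and 2.91 with low-baseline genes at their bound (camera, adjusted p = 2.3e-105 and 1.3e-107). Signalling genes rose in 9 and 11 of 16 (also 9 and 11 adjusted over the list alone, camera adjusted p = 8.7e-16 and 3.4e-16). RNA and DNA sensors rose in 5 of 7 with each (also 5 adjusted over the list alone, camera adjusted p = 2.9e-13 and 1.4e-13), with DDX58 at 4.69 ± 0.16 with H11. ISG15 conjugation genes rose in 5 of 6 and fell in 1 with each ligand, with the same counts adjusted over the list alone (camera, adjusted p = 2.1e-17 and 8.8e-18). USP18 was at 2.24 ± 0.15 with H11.

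Antigen presentation was not called as a list with either type III ligand in wild-type cells. NLRC5, the transactivator of MHC class I genes, rose by 2.99 ± 0.19 with H11, and TAPBP, the peptide-loading chaperone tapasin, by 1.85 ± 0.50, which was not called without replicate 1 of untreated wild-type cells (1.33) and was at 2.71 without replicate 2. Chemokines and IRF1-dependent genes rose in 4 of 9 with H11 and 7 of 9 with IFNL3, the same counts as adjusted over the list alone (camera, adjusted p = 0.019 and 0.018). Both of those calls were lost with an estimated correlation (adjusted p = 0.069 and 0.061 with an estimated correlation) and when only the groups compared were fitted, and the IFNL3 call also without replicate 2 of untreated wild-type cells (median 1.76).

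Targets of TGF-beta and WNT signalling and heat shock genes rose with both type III ligands in wild-type cells. The TGF-beta and WNT targets rose in 9 of 13 with each ligand (also 9 adjusted over the list alone), with medians of 1.75 and 1.78 (camera, adjusted p = 4.7e-10 and 1.0e-09). Among them CYR61, a matrix-associated signalling protein, rose 11.1-fold with H11 (3.47 ± 0.15) and 11.7-fold with IFNL3 (3.55 ± 0.15), ID1, an inhibitor of helix-loop-helix factors, by 2.66 ± 0.16 with each, and CTGF, a relative of CYR61, by 2.66 ± 0.26 with H11. IL7R, the interleukin-7 receptor chain, was 113-fold higher with H11 (counting interval 19.9 to 4478), and CRYAB, a small heat shock protein, at least 81.8-fold higher. IL7R rested on 1 untreated read and was at 6.48 on the log2 scale, or 5.58 without replicate 2 of untreated wild-type cells. Heat shock genes rose in 10 and 11 of 18 (11 with each adjusted over the list alone, camera adjusted p = 0.00012 and 0.00011). The co-chaperone DNAJA1 was at 1.505 ± 0.11 and 1.53 ± 0.11 and the chaperone HSPA1A, which has a near-identical copy, was at 1.43 ± 0.14 with H11. NEUROG2, a neurogenic transcription factor, was 15.6-fold lower with H11 and 10.3-fold lower with IFNL3, SULT2B1, a sterol sulfotransferase, 13.7-fold (-3.78, or -4.45 without H11 replicate 2) and 11.9-fold lower, and TXNIP, an inhibitor of thioredoxin, 10.4-fold lower with H11. The unfolded protein response list fell in 11 and 9 of 24 and rose in 2 with each, the same counts as adjusted over the list alone (median -0.44 and -0.25, camera adjusted p = 1.7e-05 and 4.0e-05). CHAC1 was at -2.93 ± 0.18 and -2.67 ± 0.18 and, with H11, DDIT4 at -3.14 ± 0.19 and ASNS at -1.77 ± 0.14.

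Genes of short transcripts were lower in the same 4 libraries. Ribosomal protein genes fell in 42 of 52 and rose in 1 with each ligand (43 and 1 adjusted over the list alone), with medians of -0.87 and -0.89, and RPS29 was at -2.02 ± 0.17 with H11 (camera, adjusted p = 1.9e-16 and 2.6e-17). Respiratory chain subunits fell in 27 of 40 with each (27 and 29 adjusted over the list alone, median -0.63 and -0.58, camera adjusted p = 6.6e-07 and 2.7e-07). Histone genes, whose family members share sequence, fell in 13 of 19 and rose in 1 with each (14 and 1 adjusted over the list alone, median -0.80 with each, camera adjusted p = 1.4e-07 and 5.2e-07), with HIST1H4C at -2.02 ± 0.13 with H11. Beside these groups, levels in the 4 libraries, relative to the mean of all 16, rose with transcript length (rho 0.38 to 0.41 across genes). The 50 most abundant genes took 17.7% to 18.5% of reads against 23.7% to 28.7% in the other 12 libraries. With a transcript length offset the 3 lists stayed called with smaller medians, at -0.42 and -0.47 for ribosomal proteins, -0.18 and -0.21 for the respiratory chain and -0.38 and -0.36 for histones.

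H11 changed 4932 genes in wild-type cells, 2317 up and 2615 down, and IFNL3 changed 5047, 2370 up and 2677 down. Genes named for these comparisons passed at adjusted p values of 0.0078 or less with H11 and 1.6e-06 or less with IFNL3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Between H11 and IFNL3 themselves, edgeR called 0 genes, with 158 at an unadjusted p under 0.05, and DESeq2 also called 0. Of 9880 genes over 5 CPM, 9583 had a 95% interval of this difference within 2-fold, as did 45 of the 56 antiviral effectors, whose fold changes lay between -0.79 and 0.49 around a median of -0.04.

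Set against each other in wild-type cells, IFNw gave higher levels of most antigen presentation and many antiviral genes than IFNL3, and lower levels of another set. IFI27 was 221-fold higher with IFNw (7.79 ± 0.21), ISG15 13.9-fold (3.80 ± 0.14), the viral entry inhibitor IFITM1 15.4-fold (3.95 ± 0.15), PSMB9 22.2-fold (4.47 ± 0.19) and B2M 14.9-fold (3.90 ± 0.24). A length offset lowered these to 6.59, 2.60, 2.81, 3.30 and 3.295 on the log2 scale, all still called. Antigen presentation was higher in 13 of 19 genes and lower in 1 (14 and 1 adjusted over the list alone, median 1.9998, camera adjusted p = 1.8e-12). Antiviral effectors were higher in 30 of 56 and lower in 13 (30 and 14 adjusted over the list alone, median 0.65, camera adjusted p = 5.5e-07). IL7R was at least 30.045-fold lower with IFNw, the secreted protein PI15 29.3-fold, the nuclear noncoding RNA NEAT1 13.0-fold (-3.70 ± 0.18, or -2.75 with a length offset), CYR61 7.81-fold and IRF1, a transcription factor of the interferon response, 2.53-fold. Cholesterol synthesis genes were higher in 14 of 21 (15 up and 1 down adjusted over the list alone), ribosomal protein genes in 45 of 52 (47 adjusted over the list alone, median 1.30), respiratory chain genes in 34 of 40 (35 adjusted over the list alone, median 1.10), and TGF-beta and WNT targets were lower in 9 of 13 (also 9 adjusted over the list alone), with camera adjusted p values of 9.3e-05, 4.6e-20, 1.8e-14 and 9.3e-05. The length offset lowered the medians from 0.98 to 0.64 for cholesterol synthesis, to 0.46 for ribosomal proteins and to 0.51 for the respiratory chain, all still called. These libraries differed in their length trends, with rho -0.42 and -0.43 against 0.39 in both IFNL3 libraries. Histones were higher in 12 of 19 and lower in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 0.00098), a call lost with an estimated correlation (adjusted p = 0.22 with an estimated correlation) and with the length offset, where the median went from 0.79 to -0.36. The test called 6748 genes, 3290 higher and 3458 lower, and 5374 with the length offset.

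H11 differed from IFNw in wild-type cells in the same kinds of genes, a comparison added after the data were seen. IFI27 was 234-fold lower with H11 (-7.87 ± 0.21), PSMB9 27.1-fold (-4.76 ± 0.19) and ISG15 13.3-fold (-3.73 ± 0.14), while NEAT1 was 13.6-fold higher (3.77 ± 0.18) and CYR61 7.39-fold (2.89 ± 0.14). These libraries differed in their length trends too, with rho 0.38 and 0.41 for H11, and a length offset moved IFI27 to -6.68, PSMB9 to -3.59, ISG15 to -2.53 and NEAT1 to 2.82, all still called. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6632 genes, 3373 higher and 3259 lower with H11. Antiviral effectors were lower in 29 of 56 and higher in 12 (30 and 13 adjusted over the list alone, median -0.79, camera adjusted p = 7.5e-08). Across the antiviral genes this difference rose with transcript length (rho 0.68, and 0.51 with the offset).

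In optimized cells, IFNw and H11 gave responses with no gene called between them. IFI27 rose by 12.42 ± 0.29 with IFNw and 12.33 ± 0.29 with H11, from 9 reads in the untreated group, and ISG15 rose 486-fold (8.92 ± 0.18) and 461-fold (8.85 ± 0.18). IFI27 was at 11.73 and 11.69 and ISG15 at 8.23 and 8.19 with a length offset. Without replicate 1 of untreated optimized cells IFI27 was at 13.12 and 13.03. IRF9 rose by 4.87 ± 0.17 and 4.90 ± 0.17. IFI44 was at least 1818-fold and 1923-fold higher, and OAS1, on 2 untreated reads, 3466-fold (counting interval 959 to 28623) and 3575-fold (989 to 29523). Antiviral effectors rose in 53 of 56 with each ligand and 0 fell, also 53 adjusted over the list alone, with medians of 4.5002 and 4.53, or 4.002 and 4.06 with low-baseline genes at their bound (camera, adjusted p = 5.0e-159 and 3.4e-160). Antigen presentation rose in 18 and 17 of 19 (18 with each adjusted over the list alone, median 2.25 and 2.23, camera adjusted p = 2.0e-34 and 9.6e-33). B2M was at 4.13 ± 0.24 and 4.17 ± 0.24 (4.81 and 4.85 without that library), PSMB9 at 4.02 ± 0.19 and 3.97 ± 0.19 (3.35 and 3.33 with a length offset) and the peptide transporter TAP1 at 3.21 ± 0.13 with IFNw. ISG15 conjugation rose in 6 of 6 with each (also 6 adjusted over the list alone, camera adjusted p = 4.3e-38 and 2.2e-39). Signalling genes rose in 9 and fell in 2 of 16 with each, the same counts as adjusted over the list alone (camera, adjusted p = 1.2e-12 and 2.7e-13). Of 7 sensors 5 rose and 1 fell with each, also adjusted over the list alone (camera, adjusted p = 7.7e-10 and 2.0e-10). Of 9 chemokines and IRF1-dependent genes 7 rose with each (8 and 7 adjusted over the list alone, camera adjusted p = 0.0019 and 0.0025).

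Metabolic and stress genes changed in the same cells. Cholesterol synthesis rose in 16 of 21 and fell in 1 with each (16 and 17 up adjusted over the list alone, median 0.70 and 0.73, camera adjusted p = 2.8e-06 and 2.2e-06). IDI1 was at 1.94 ± 0.11 and 1.91 ± 0.11 and squalene synthase, FDFT1, at 1.45 ± 0.30 with each (2.45 without replicate 1 of untreated optimized cells). CHAC1 was 17.2-fold lower with IFNw and 16.3-fold with H11, SLC7A11 7.44-fold and 7.13-fold, and STC2 6.27-fold with IFNw. The unfolded protein response list, with 7 up in each and 8 and 9 down of 24 (7 up and 9 down in each adjusted over the list alone), had medians of -0.17 and -0.26 (camera, adjusted p = 0.0096 and 0.0058) and was not called without the low-count filter. With IFNw its median was -0.28 with a length offset. Heat shock genes rose in 8 and 9 of 18, the same as adjusted over the list alone (camera, adjusted p = 0.00015 and 0.00017), with DNAJA1 and its relative DNAJB1 at 1.72 ± 0.11 and 1.70 ± 0.18 with IFNw. Ribosomal protein genes rose in 26 and 24 of 52 (26 and 27 adjusted over the list alone) and respiratory chain genes in 23 and 22 of 40 (25 and 23 adjusted over the list alone), beside length trends of rho -0.41 to -0.44 in these 4 libraries. With a length offset the ribosomal call ended with both ligands, its medians going from 0.43 to -0.10 and from 0.37 to -0.12, and the respiratory chain call ended with H11, its median going from 0.50 to 0.20 (0.55 to 0.22 with IFNw, still called).

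IFNw changed 4247 genes in optimized cells, 2226 up and 2021 down, and H11 changed 4116, 2185 up and 1931 down. Fitted on the compared groups alone the counts were 2052 (1298 up and 754 down) and 2021 (1256 up and 765 down). Named genes passed at adjusted p values of 0.0013 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Between H11 and IFNw, a comparison added after the data were seen, edgeR called 0 genes, with 279 at an unadjusted p under 0.05, and DESeq2 called 0. Of the 9880 genes over 5 CPM, 9393 had an interval of this difference within 2-fold, as did 49 of the 56 antiviral effectors.

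IFNL3 raised antiviral and antigen presentation genes in optimized cells too. ISG15 rose 282-fold (8.14 ± 0.18), IFI27 by 10.84 ± 0.28 from 9 reads, and IRF9 19.7-fold (4.30 ± 0.16). Without replicate 1 of untreated optimized cells IFI27 was at 11.54 and B2M at 3.46. Antiviral effectors rose in 51 of 56 and 0 fell (52 adjusted over the list alone), with a median of 4.10, or 3.68 with low-baseline genes at their bound (camera, adjusted p = 1.8e-275). Antigen presentation rose in 13 of 19 (16 adjusted over the list alone, median 1.42, camera adjusted p = 1.5e-29), with B2M at 2.78 ± 0.23, PSMB9 at 2.64 ± 0.18 and TAP1 at 2.23 ± 0.12. ISG15 conjugation rose in 6 of 6 (also 6 adjusted over the list alone), signalling genes in 8 of 16 (11 adjusted over the list alone), sensors in 5 of 7 with 1 lower (the same adjusted over the list alone) and chemokines and IRF1-dependent genes in 5 of 9 (also 5 adjusted over the list alone), with camera adjusted p values of 9.9e-67, 8.7e-26, 9.8e-19 and 8.7e-05. Cholesterol synthesis rose in 14 of 21 (16 up and 1 down adjusted over the list alone, camera adjusted p = 1.1e-09), with the pathway's synthase HMGCS1 at 1.34 ± 0.15 and IDI1 at 1.22 ± 0.11.

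Stress, hypoxia and histone genes changed as well with IFNL3 in optimized cells. Heat shock genes rose in 10 of 18 (11 adjusted over the list alone, camera adjusted p = 1.4e-10). Hypoxia and glycolysis genes rose in 10 of 24 and fell in 2 (11 and 3 adjusted over the list alone, median 0.33, camera adjusted p = 0.017). Histones fell in 11 of 19 and rose in 1 (13 and 1 adjusted over the list alone, median -0.75, camera adjusted p = 1.1e-10). The unfolded protein response list fell in 8 of 24 and rose in 5, also adjusted over the list alone (camera, adjusted p = 2.4e-07), with CHAC1 20.3-fold lower and INHBE at -6.31 ± 0.45 on 4 reads. EGR3, an early growth response transcription factor, rose from 1.35 ± 0.68 to 7.99 ± 0.06 CPM (2.46 ± 0.39, or 3.17 without replicate 1 of untreated optimized cells).

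IFNL3 changed 1690 genes in optimized cells, 922 up and 768 down, the named ones at an adjusted p of 0.00041 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Single libraries moved this count, to 3127 without replicate 1 and 978 without replicate 2 of untreated optimized cells, and to 680 and 785 without replicate 1 or 2 of optimized cells with IFNL3. It was 225 when only the compared groups were fitted.

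H11 and IFNL3 differed in optimized cells. Higher with H11 were IFI27 2.81-fold (1.49 ± 0.16), IFIT1 1.98-fold (0.99 ± 0.12), B2M 2.62-fold (1.39 ± 0.22), PSMB9 2.52-fold (1.33 ± 0.16) and GBP1, an interferon-induced GTPase, 12.7-fold (3.66 ± 0.72). GBP1 had 9 reads with IFNL3, all in replicate 1, and was at 2.73 without replicate 2. Lower with H11 were the early growth response factors EGR1 (-1.81 ± 0.36), EGR2 (-2.07 ± 0.41) and EGR3 (-1.68 ± 0.36), ETV5, a transcription factor downstream of growth factor signalling (-2.70 ± 0.47), and HERC5 (-0.56 ± 0.14). ISG15 (0.71 ± 0.13) and IRF9 (0.60 ± 0.12) passed too, but with a length offset they were not called, at 0.16 and 0.39. HERC5 was not called without H11 replicate 2 (-0.45) or IFNL3 replicate 1 (-0.42). Without H11 replicate 2, EGR3 was not called at -1.35, and without IFNL3 replicate 2, IRF9 was not called at 0.50. Antiviral effectors were higher in 16 of 56 and lower in 3 (16 and 5 adjusted over the list alone, median 0.10, camera adjusted p = 0.034), a call lost with an estimated correlation (adjusted p = 0.12 with an estimated correlation) and without H11 replicate 1 (median 0.10), IFNL3 replicate 2 (0.08) or the low-count filter (0.06), or in a fit of the compared groups alone (0.10). Antigen presentation was higher in 9 of 19 (9 up and 1 down adjusted over the list alone, median 0.66, camera adjusted p = 1.7e-09).

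IFNw also differed from IFNL3 in optimized cells, with IFIT1 at 0.97 ± 0.12, ISG15 at 0.78 ± 0.13, B2M at 1.35 ± 0.22, PSMB9 at 1.39 ± 0.16, GBP1 at 3.63 ± 0.72 (2.70 without IFNL3 replicate 2, which had 0 reads), EGR1 at -1.80 ± 0.35 and HERC5 at -0.65 ± 0.14. ISG15 was not called with a length offset (0.20). HERC5 was not called without IFNL3 replicate 1 (-0.51) or IFNw replicate 2 (-0.52). Antiviral effectors were higher in 17 of 56 and lower in 5, also adjusted over the list alone (median 0.11, camera adjusted p = 0.017, and adjusted p = 0.089 with an estimated correlation). Antigen presentation was higher in 9 of 19 (10 adjusted over the list alone, median 0.85, camera adjusted p = 3.8e-11). In both comparisons histones (10 and 13 of 19 higher, 14 and 16 adjusted over the list alone), ribosomal proteins (30 and 33 of 52, 34 and 40 adjusted over the list alone) and respiratory chain genes (18 and 19 of 40, 21 and 23 adjusted over the list alone) were higher than with IFNL3, beside length trends of rho -0.41 to -0.44 against 0.06 and 0.09 in the IFNL3 libraries. With the length offset the histone and ribosomal calls ended in both (histone medians 0.09 and 0.17, ribosomal 0.11 and 0.16), and the respiratory chain stayed called with medians going from 0.45 to 0.09 and from 0.54 to 0.17.

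The 2 comparisons with IFNL3 in optimized cells called 2232 genes for H11 (1360 higher and 872 lower, 213 over 2-fold) and 2422 for IFNw (1459 higher and 963 lower, 284 over 2-fold). With the length offset the counts were 979 and 1132. The H11 count was 1213 and 1122 without H11 replicate 1 or 2 and 1196 and 1046 without IFNL3 replicate 1 or 2. The IFNw count was 1510 and 1243 without IFNw replicate 1 or 2 and 1302 and 1246 without IFNL3 replicate 1 or 2. Adjusted p values of named genes reached 0.0097 and 0.0034 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

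**Figure D2:**
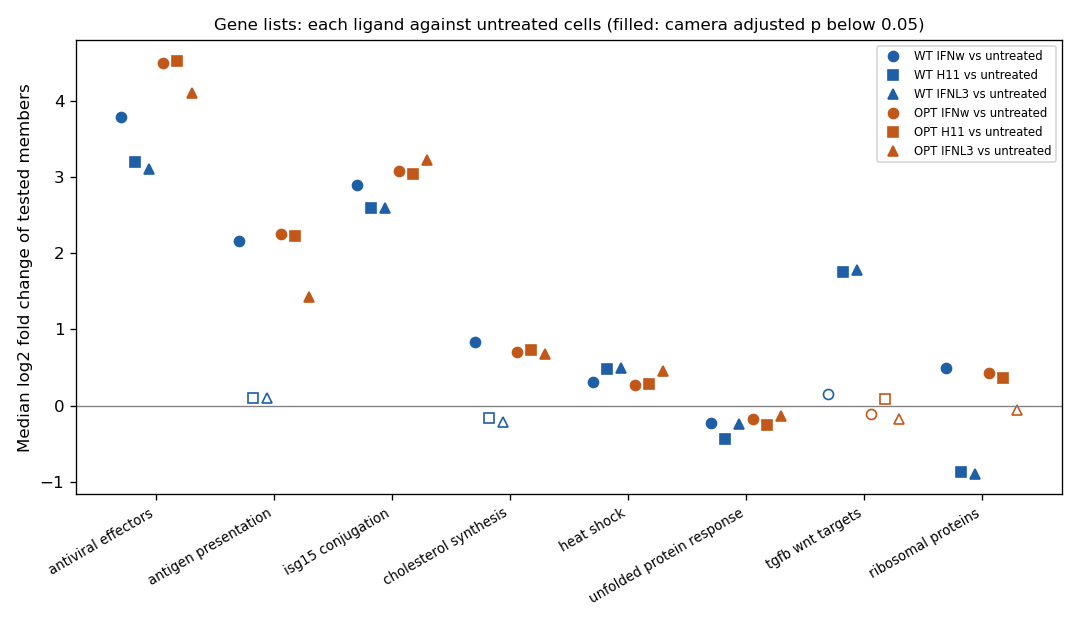
Median log2 fold change against untreated cells of 8 gene lists in the 6 ligand comparisons, with circles for IFNw, squares for H11 and triangles for IFNL3, blue for wild-type and orange for optimized cells, and filled symbols where camera's adjusted p was below 0.05. The antiviral medians lie between 3.11 and 4.53 in all 6, while TGF-beta and WNT targets are filled only with H11 and IFNL3 in wild-type cells, at 1.75 and 1.78, and the ribosomal medians are negative there (-0.87 and -0.89), against 0.50 with IFNw.

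Whether the genotypes differed before a ligand was added, and after IFNw, was tested directly. Between untreated optimized and wild-type cells edgeR called 0 genes, with 705 at an unadjusted p under 0.05, and DESeq2 called 0. The count went to 1280 without replicate 1 of untreated optimized cells, which left the shallowest library alone in that group, and to 1 without replicate 1 of untreated wild-type cells. With IFNw edgeR called 0 genes between genotypes, with 439 at an unadjusted p under 0.05, and DESeq2 called 0. Of 9880 genes over 5 CPM, 9132 and 9283 had an interval of the difference within 2-fold in untreated and IFNw-treated cells, and 35 and 47 of the 56 antiviral effectors did. In data simulated for the IFNw comparison, 72.2% of 2-fold changes and 99.7% of 4-fold changes were recovered. The changed genes there had 5 CPM or more in untreated wild-type cells. These shares do not cover genes below that level, or antiviral genes at the levels reached with IFNw. For the difference between the genotypes' responses to IFNw, 0 genes were called by edgeR, 633 at an unadjusted p under 0.05 and 0 by DESeq2, with 7135 of the 9880 genes and 22 of the 56 antiviral effectors within 2-fold, so larger differences are less well excluded here. Counts of 761 and 1 were reached without replicate 1 of untreated optimized or untreated wild-type cells.

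With H11 the genotypes differed in antiviral and antigen presentation genes. IFI27 was 191-fold higher in optimized than in wild-type cells (7.58 ± 0.21), PSMB9 24.5-fold (4.62 ± 0.19), IFITM3 15.0-fold and IFITM1 14.4-fold (3.90 ± 0.17 and 3.85 ± 0.15), B2M 14.9-fold (3.89 ± 0.24) and ISG15 12.2-fold (3.61 ± 0.14). The ISG15-conjugating enzyme UBE2L6 was at 2.96 ± 0.16 and the sensor DHX58 at 2.71 ± 0.25. These differences shrank with a length offset, to 6.41 for IFI27, 3.47 for PSMB9, 2.77 for IFITM3, 2.74 for IFITM1, 3.30 for B2M, 2.43 for ISG15 and 2.14 for UBE2L6, and all of them stayed called. Not every interferon gene was higher, with DDX58 at -0.86 ± 0.14, IRF1 at -1.02 ± 0.19 and IFIH1 at -0.55 ± 0.19, the last not called with a length offset (-0.45) or with any of the 4 compared libraries left out (-0.62 and -0.46 without replicate 1 or 2 of optimized cells, -0.55 and -0.57 without replicate 1 or 2 of wild-type cells). Antiviral effectors were higher in 30 of 56 and lower in 13 (32 and 13 adjusted over the list alone, median 0.69, camera adjusted p = 4.7e-08). The difference fell with transcript length across the antiviral genes (rho -0.70, and -0.54 with the offset). Antigen presentation was higher in 14 of 19 and lower in 2, also adjusted over the list alone (median 1.94, camera adjusted p = 3.8e-13), and ISG15 conjugation in 5 of 6 (also 5 adjusted over the list alone, camera adjusted p = 2.9e-05). IL7R was at least 28.9-fold lower, PI15 56.0-fold, NEAT1 11.3-fold (-3.50 ± 0.18), CYR61 7.97-fold and ID1 3.73-fold (-1.90 ± 0.16). The offset moved NEAT1 to -2.58 and ID1 to -2.94.

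Metabolic lists differed between the genotypes with H11 too. Cholesterol synthesis was higher in 13 of 21 (also 13 adjusted over the list alone, camera adjusted p = 0.00032), with IDI1 at 2.14 ± 0.11 and INSIG1, a sterol-sensing regulator, at 1.90 ± 0.19. Ribosomal proteins were higher in 45 of 52 and respiratory chain genes in 34 of 40, the same counts as adjusted over the list alone (camera, adjusted p = 8.0e-20 and 5.9e-14), with RPS27 at 3.10 ± 0.17, or 1.88 with a length offset. The offset lowered the medians from 1.23 to 0.497 for ribosomal proteins, from 1.07 to 0.25 for the respiratory chain and from 0.94 to 0.44 for cholesterol synthesis, all still called. TGF-beta and WNT targets were lower in 8 of 13, also adjusted over the list alone (median -1.05, camera adjusted p = 4.3e-05). Histones were higher in 12 of 19 and lower in 1, also adjusted over the list alone (camera, adjusted p = 0.00077), which was lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation) and turned with the length offset, from a median of 0.78 to -0.25. Beside these lists stands the length trend, with a median difference of 0.74 in the shortest and -0.62 in the longest of 5 equal groups of transcripts. SULT2B1 was 23.4-fold higher (4.55 ± 0.36, or 3.71 with a length offset and 5.22 without replicate 2 of wild-type cells).

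With H11, 3251 genes were higher and 3314 lower in optimized cells, 6565 in all and 5326 with the length offset, of which 4058 were called in the same direction in both fits. The response to H11 relative to untreated cells differed between genotypes in 4690 genes, 2480 higher and 2210 lower. ISG15 (3.83 ± 0.20), IFITM1 (4.22 ± 0.26), B2M (4.54 ± 0.31) and IFI27 (6.47 ± 1.01, on 5 and 9 untreated reads) had larger responses in optimized cells and CYR61 (-2.98 ± 0.21) a smaller one. Without replicate 1 of untreated wild-type cells IFI27 was not called, at 5.197. It was at 7.18 without replicate 2 of those cells and 7.17 without replicate 1 of untreated optimized cells, where B2M was at 5.22. A length offset lowered the differences to 2.64 for ISG15, 3.09 for IFITM1, 3.93 for B2M and 5.28 for IFI27, all still called. The named genes passed at an adjusted p of 0.021 or less in the first and 9.8e-05 or less in the second test by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

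With IFNL3 the genotypes differed as well, in antiviral, antigen presentation and TGF-beta and WNT target genes. IFI27 was 64.1-fold higher in optimized cells (6.0015 ± 0.19), IFITM1 9.59-fold (3.26 ± 0.14), PSMB9 8.0004-fold (3.0001 ± 0.18), ISG15 7.84-fold (2.97 ± 0.14) and B2M 5.90-fold (2.56 ± 0.22). The first 4 fell with a length offset to 5.37, 2.63, 2.37 and 2.34 on the log2 scale, all still called. EGR3 was 9.25-fold higher (3.21 ± 0.40). Lower were IRF1 (-1.45 ± 0.19), DDX58 (-0.57 ± 0.13), CYR61 (-2.85 ± 0.14) and ID1 (-2.74 ± 0.16, or -3.35 with a length offset), and the matrix protein TNC was 59.7-fold lower (counting interval 16.2 to 498). TNC had 2 reads in optimized cells with IFNL3 and was at -5.73 on the log2 scale, or -4.87 without replicate 2 of those cells. Antiviral effectors were higher in 23 of 56 and lower in 9 (24 and 9 adjusted over the list alone, median 0.31, camera adjusted p = 1.1e-09). Across the antiviral genes this difference fell with transcript length (rho -0.61, and -0.50 with the offset). Antigen presentation was higher in 12 of 19 and lower in 2 (13 and 2 adjusted over the list alone, median 1.13, or 0.71 with a length offset, camera adjusted p = 3.8e-11) and ISG15 conjugation in 5 of 6 (6 adjusted over the list alone, camera adjusted p = 9.1e-09). Cholesterol synthesis was higher in 17 of 21 (19 adjusted over the list alone), ribosomal proteins in 44 of 52 (46 adjusted over the list alone) and respiratory chain genes in 27 of 40 (29 adjusted over the list alone), and TGF-beta and WNT targets lower in 8 of 13 (10 adjusted over the list alone), with camera adjusted p values of 4.5e-08, 9.1e-18, 3.1e-11 and 8.2e-11. The length offset lowered the ribosomal median from 0.72 to 0.33 and the respiratory chain median from 0.64 to 0.35, both still called. The wild-type libraries in this comparison had length trends of rho 0.39 and the optimized ones 0.06 and 0.09.

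In total 4220 genes differed between genotypes with IFNL3, 2300 higher and 1920 lower in optimized cells, and 2807 without replicate 1 of wild-type cells with IFNL3. The response to IFNL3 differed in 2338 genes, 1409 higher and 929 lower, or 1603 (781 and 822) with the length offset, 1508 without replicate 2 of wild-type cells with IFNL3, 1547 without replicate 1 of optimized cells with IFNL3 and 1538 in a fit of the 4 groups alone. Responses differed for ISG15 (3.19 ± 0.20), IFITM1 (3.64 ± 0.26), B2M (3.21 ± 0.31), IFI27 (4.89 ± 0.94, on 5 and 9 untreated reads), EGR3 (3.99 ± 0.58) and CYR61 (-2.83 ± 0.21). IFI27 was not called without replicate 1 of untreated wild-type cells (3.62). A length offset lowered ISG15 to 2.54, IFITM1 to 2.98 and IFI27 to 4.24, all still called. Without replicate 1 of untreated optimized cells B2M was at 3.89, EGR3 at 4.70 and IFI27 at 5.59, and IFI27 at 5.60 without replicate 2 of untreated wild-type cells. All adjusted p values for named genes were at most 0.0037 for the difference and 0.0017 for the response by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

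Averaged over the 4 treatments, 8 libraries of each genotype, antigen presentation was higher in optimized cells in 12 of 19 genes and lower in 2 (13 and 2 adjusted over the list alone, median 0.78, camera adjusted p = 3.5e-13). ISG15 conjugation was higher in 4 of 6 (also 4 adjusted over the list alone), cholesterol synthesis in 14 of 21 (also 14 adjusted over the list alone, median 0.38), ribosomal proteins in 45 of 52 (46 adjusted over the list alone, median 0.47) and respiratory chain genes in 29 of 40 (also 29 adjusted over the list alone), while TGF-beta and WNT targets were lower in 8 of 13 (also 8 adjusted over the list alone, median -0.50), with camera adjusted p values of 1.1e-05, 2.1e-05, 2.0e-20, 4.4e-14 and 1.7e-06. The length offset lowered the ribosomal median to 0.22 and the respiratory chain median from 0.40 to 0.16, both still called. Antiviral effectors were not called (median 0.18, camera adjusted p = 0.19). Histones, at a median of 0.23 with 10 of 19 higher and 1 lower, also adjusted over the list alone, were called by camera (adjusted p = 0.037) but not with an estimated correlation (adjusted p = 0.42 with an estimated correlation) nor without 1 of 6 libraries (medians 0.16 to 0.28), and turned to -0.11 with the length offset. Those 6 were replicate 2 of optimized cells untreated, with H11 or with IFNL3, and replicate 1 of wild-type cells untreated, with IFNw or with H11. The average difference was called in 5458 genes, 2812 higher and 2646 lower, 371 of them over 2-fold.

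The lists of genes called against untreated cells overlapped between genotypes and ligands to different extents. For IFNw, wild-type and optimized cells shared 1684 higher and 1234 lower genes, where independent lists would share 370 and 299. For H11 they shared 359 and 465, against 399 and 397, and for IFNL3 365 and 448, against 172 and 162. No length offset was applied to these overlaps. With H11 the fold changes followed transcript length in opposite directions (rho 0.25 in wild-type and -0.36 in optimized cells, across genes). The H11 overlap alone therefore does not show unrelated responses, and most antiviral effectors rose in both genotypes. Within wild-type cells H11 and IFNL3 shared 2044 higher and 2320 lower genes (432 and 551 if independent) and IFNw and H11 shared 369 and 465 (385 and 387). Within optimized cells IFNw and H11 shared 1972 and 1581 (383 and 307) and H11 and IFNL3 710 and 512 (159 and 117). Ligands of a genotype share their untreated libraries. In simulated unchanged groups, 2 ligands shared 0 genes on average in wild-type and 0.05 in optimized cells. All simulated libraries, of both genotypes, were drawn from the levels of untreated wild-type cells with the same spread per gene in every group. The larger spread between the untreated optimized libraries (chi-square per degree of freedom 24.6) was thus not simulated, and the shared controls may give more there. Part of an excess may still come from the shared controls, since 2 libraries cannot be split into separate control groups of 2.

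Several lists were called in no comparison. The smallest camera adjusted p was 0.10 for genes of mitosis (25 tested), 0.15 for DNA replication (25), 0.080 for p53 targets (19), 0.088 for NF-kappaB targets (13), 0.10 for immediate early genes (23), 0.40 for cell death and growth arrest genes (11), 0.46 for fibroblast markers (7) and 0.22 for neuronal genes (8). Markers of blood cells, with 2 tested genes, and of hepatocytes and keratin-rich epithelium, with 1, were too few for a list test, and none of the interferon genes was tested.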

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

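The tests of the difference between responses were planned, as was the count over other splits of the libraries, while the tests of transcript length, depth, collagen genes, a shared batch and mixtures were chosen after the patterns were seen.

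The response to H11 differed between optimized and wild-type cells by a test of the difference itself in 4690 genes. Larger responses in optimized cells were found for ISG15 (log2 difference 3.83), IFITM1 (4.22), B2M (4.54) and IFI27 (6.47), and a smaller one for CYR61 (-2.98). These shrank with a length offset, to 2.64 for ISG15, 3.09 for IFITM1, 3.93 for B2M and 5.28 for IFI27. Among gene lists, the median difference was 1.48 for ISG15 conjugation, 1.94 for antigen presentation, 0.83 for cholesterol synthesis, 1.19 for ribosomal proteins, 0.98 for the respiratory chain and -1.60 for TGF-beta and WNT targets. The offset lowered these medians to 0.48 for cholesterol synthesis, 0.44 for ribosomal proteins and 0.30 for the respiratory chain, all still called. Histones had a median difference of 0.71, not called with an estimated correlation (adjusted p = 0.29 with an estimated correlation), and turned to -0.29 with the length offset.

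The response to IFNL3 differed between the genotypes in 2338 genes by the same kind of test. Gene values were 3.19 for ISG15, 3.64 for IFITM1, 3.21 for B2M, 4.89 for IFI27, 3.99 for EGR3 and -2.83 for CYR61. ISG15 was at 2.54, IFITM1 at 2.98 and IFI27 at 4.24 with a length offset. List medians were 1.20 for ISG15 conjugation, 1.20 for antigen presentation, 0.72 for cholesterol synthesis, 0.71 for ribosomal proteins, 0.58 for the respiratory chain and -2.00 for TGF-beta and WNT targets. The ribosomal and respiratory chain medians were 0.27 and 0.25 with the offset, both still called. Hypoxia and glycolysis had a median of 0.14, not called with an estimated correlation (adjusted p = 0.086 with an estimated correlation), without replicate 2 of untreated wild-type cells (0.12), without replicate 1 of wild-type cells with IFNL3 (0.13) or without replicate 2 of optimized cells with IFNL3 (0.24).

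Relative to the mean of all 16 libraries, levels rose with transcript length in the 4 wild-type libraries with H11 or IFNL3 (rho 0.38 to 0.41 across genes). They fell with it in the 6 libraries of IFNw in both genotypes and H11 in optimized cells (rho -0.41 to -0.44). The untreated libraries lay between them (0.08 to 0.16). Sign and size depend on the groups that make up the mean. The values do not show which of the treated sets deviates, and both enter the contrasts between them.

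A set of 29 genes outside the interferon lists (16 higher and 13 lower) separated the 4 wild-type libraries with H11 or IFNL3 from every other library by at least 3-fold, against 9 for the untreated libraries and 0 for any other pair of groups. Only pairs of groups were counted. The groups with IFNw in both genotypes and with H11 in optimized cells were alike, so no pair of them could stand apart from the remaining one. The count therefore does not show that the 4 wild-type libraries deviate more than that set. With the length offset, 64.2% of the genes of known length called between genotypes with H11 stayed called in the same direction. The offset follows the average trend of genes outside the interferon lists, and antiviral differences still fell with length after it (rho -0.54). The share therefore does not show how much of the pattern the length trend accounts for. Lower depth is argued against by a ratio of mean total reads of 1.02, and RNA of fibroblast-like cells by the summed level of the collagen genes COL1A1, COL1A2 and COL3A1, which changed by -4.37 CPM relative to untreated wild-type cells. A separate culture or library batch of these 4 libraries cannot be told apart from an effect of type III ligands through wild-type receptors, because it would coincide with these groups, and 0 genes were called between H11 and IFNL3. Both may act, and a test would repeat all 8 groups in a single batch with the order of libraries drawn at random.

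Optimized cells with IFNL3 lay between wild-type cells with IFNL3 and optimized cells with H11. Of 1320 genes called against both, 6.14% lay outside their range, 33 above and 48 below, which leaves a mixture of RNA of these 2 kinds neither excluded nor shown. For a mixture of untreated and fully responding cells, 40.8% of 515 genes called against both untreated cells and cells with H11 lay outside their range. This goes against such a mixture only if non-responding cells in a treated culture match the untreated cultures. The design cannot show that without a mock-treated group, so the test does not decide. A weaker signal from the unmodified ligand through optimized receptors is a candidate explanation that no test here addressed. It could be tested with a dose series of both ligands and staining of single cells, which would also tell a mixture from a weaker response of every cell.

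For the average difference between genotypes, 4 of 100 splits of the libraries within treatments, the real one included, called as many genes as the real 5458, with 5516 as the highest other value. Of the 100 drawn, 7 kept the H11 and IFNL3 libraries divided by genotype and called at least 5309 genes, while no other drawn split called more than 2. Such splits make up 36 of the 648 possible, so the count rests on the H11 and IFNL3 libraries. The split by replicate number called 29 genes.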

How the results depend on the processing

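The length offset and the fit without the wild-type libraries with H11 and IFNL3 were chosen after the data were seen, all other alternatives before. Over all alternatives, 1738 values of genes named in the text kept their direction and call, 18 lost the call and 0 reversed. For called gene lists other than the antiviral effectors, 1304 values kept theirs, 31 lost the call and 6 reversed. A list's direction is the one camera gives, which can differ from the sign of its median. Losses of the antiviral list are given below and come on top of these. DESeq2 gave no adjusted p for 5 named values, which are not counted. The number of list calls was 128, and 118 with an estimated correlation, 128 with DESeq2's size factors, 129 without the low-count filter, 126 with a replicate block and 135 with the length offset. Where a cause is not evident from fewer libraries or genes, the cause was not tested. Depth limits genes near 0 reads in untreated cells, and the shallowest library, replicate 2 of untreated optimized cells, limits comparisons with that group.

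Counts that moved by more than 1.5 times were as follows. Fitting only the compared groups gave 2052 for IFNw, 2021 for H11 and 225 for IFNL3 against untreated optimized cells, and 1538 for the difference in response to IFNL3. Without the low-count filter 50 genes were called between untreated genotypes, 15 for the difference in response to IFNw and 1 between H11 and IFNL3 in wild-type cells. The length offset gave 979 for H11 and 1132 for IFNw against IFNL3 in optimized cells. With 1 library left out, the counts ranged from 2630 to 2853 for IFNw in wild-type cells, 680 to 3127 for IFNL3 in optimized cells, 0 to 1280 between untreated genotypes and 2807 to 2839 between genotypes with IFNL3. They ranged from 0 to 761 and 1508 to 3388 for the differences in response to IFNw and IFNL3, and 1046 to 1213 and 1243 to 1510 for H11 and IFNw against IFNL3 in optimized cells.

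The antiviral list lost its call for H11 against IFNL3 in optimized cells with an estimated correlation (median 0.10, adjusted p 0.12), without the low-count filter (0.058), with a replicate block (0.10) and with the compared groups alone (0.10), and ranged from 0.082 to 0.23 with 1 library left out. Its adjusted p lay between 0.010 and 0.12 over all alternatives. For IFNw against IFNL3 there the call was lost with an estimated correlation (median 0.11, adjusted p 0.089, range 0.0037 to 0.089). Reversals of camera's direction occurred with the length offset only, for ribosomal proteins with IFNw in wild-type cells (-0.088) and for histones between genotypes with H11 (-0.25), in the difference in response to H11 (-0.29), for IFNw against IFNL3 (-0.36) and H11 against IFNw (0.22) in wild-type cells and for the average (-0.11). The ribosomal medians also turned negative with the offset for IFNw (-0.097) and H11 (-0.12) in optimized cells, where camera's direction stayed and the call was lost.

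In a replicate block, counts rose to 4596, 5658 and 5695 for IFNw, H11 and IFNL3 in wild-type cells and to 4858, 4761 and 2499 in optimized cells, and stayed at 0 where they were 0. The hypoxia and glycolysis list was not called in the difference in response to IFNL3 with the replicate block (median 0.15). The replicate numbers are not taken to pair the libraries, since the labels say nothing of a shared day or batch. Deviations of same-numbered libraries correlated at 0.14 to 0.37 over 28 pairs of groups (median 0.28, 8905 genes), a hint from the data only, and 812 genes were called between replicates 1 and 2.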

Other observations

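The list of amino-acid response genes and all its tests were chosen after the values were seen, as were the genes named for IFNL3 in optimized cells.

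Untreated cells of both genotypes had higher levels of genes that the transcription factor ATF4 activates when amino acids are short. A list of 37 such genes, written after many of them were seen to be lower with a ligand, had 36 tested members, of which 31 to 34 fell and at most 1 rose in each of the 6 ligand comparisons, with medians from -1.29 to -1.52. No p-value is given, because these values follow in part from the choice of the genes. CHAC1, which degrades glutathione, went from 105 ± 4.53 CPM in untreated wild-type cells to 6.11 ± 1.95 with IFNw, 13.8 ± 1.49 with H11 and 16.5 ± 0.23 with IFNL3. ASNS, asparagine synthetase, went from 397 ± 19.99 to 105 ± 1.64, 116 ± 3.44 and 113 ± 5.94 CPM. DDIT4, an inhibitor of growth signalling, went from 114 ± 5.03 to 31.2 ± 0.44, 12.9 ± 1.95 and 13.3 ± 2.25 CPM.

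A hypothesis is that the untreated cultures were short of amino acids relative to all treated ones, for example through a different medium change or culture age. Another is that each ligand lowers ATF4 output, and the design cannot separate them because no mock-treated group is among the libraries used here. With the length offset the list was called lower in 6 of 6 ligand comparisons, but these calls are no support, since the genes were chosen for their falls. Its medians with the offset lay between -1.26 and -1.64, against -1.29 to -1.52 without it. For the genes chosen, these sizes argue against the transcript length trend as the source of the falls. A single deviating untreated library is argued against too, since the list's mean log2 CPM in 4 of 4 untreated libraries (6.56 to 6.59) lay above all 12 treated libraries (4.85 to 5.196). A test would add mock-treated cultures with the same medium change and harvest, in which ASNS and CHAC1 should be as low as with a ligand under the first hypothesis.

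EGR3 and CCL20 had their highest levels in optimized cells with IFNL3, while the immediate early and NF-kappaB lists were called in no comparison. EGR3, an early growth response factor, was at 7.99 ± 0.06 CPM, against 1.35 ± 0.68 in untreated optimized cells, and CCL20, a chemokine, had 31 reads (1.67 ± 0.48 CPM) against 0 in untreated optimized cells, at least 8.55-fold higher.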
